A study of Mus musculus with 6 samples.

How the data were processed

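RNA was extracted from mouse crypt epithelium, messenger RNA was purified with poly-T beads and libraries were made from randomly primed cDNA and sequenced on an Illumina platform, per the labels' protocols. The series has 6 libraries in 2 groups, 3 from β-catenin GOF/+ crypts and 3 from controls, at 4 days after induction. Groups and replicate numbers were taken from the sample titles, and table columns were matched to samples by group and replicate number. The mutant columns carry a name that marks a heterozygous exon change, which was matched to the only group not named control.

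The deposited values of the 24930 genes are a signal, a normalized abundance per gene that was made by the authors. Per the submitters' processing notes, kallisto 0.46.1, DESeq2 1.40.1 and the mm9 genome build were used; the notes give no role or order for them, and the annotation, filters and the step that made the values are not given in the sources used here. The values were checked for their unit. They are not counts, since 0% of values above 0 are whole numbers, and not a per-million unit, since library totals ranged from 645225 to 1268771 units. The median ratio of a library to the geometric mean over libraries lay between 0.990 and 1.01, so the libraries had been put on a common scale. Below 0.3 units, ratios between libraries fell in steps, as whole reads divided by a gene's length would give. The steps yielded the relative reads per unit of each library, set to 1 in control replicate 1: 1.03 and 1.42 in control replicates 2 and 3, and 0.996, 1.35 and 0.886 in mutant replicates 1 to 3, a 1.61-fold range. Whole counts could not be recovered, because the step depends on gene length. Absolute depth is therefore unknown, no counting interval is given, and low values carry more counting error in mutant replicate 3 than elsewhere. Of all genes, 5728 are at 0 in every library and 24 rows carry calendar dates in place of gene symbols, and 0 value columns lacked a sample.

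Each value x was transformed to log2(x + 1). Genes with a mean of at least 1 unit over the 6 libraries were tested (11837 genes) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, group as the single term and Benjamini-Hochberg adjustment at 0.05. Log2 differences are on the log2(value + 1) scale and understate the change of low genes. A count model had been planned for a table of counts and was not run, because the table holds normalized values; the limma test is the one laid down beforehand for that case. 27 gene lists were fixed before the data were examined, and the 23 with at least 3 tested members were compared with camera at its preset correlation of 0.01, adjusted over the lists. List scores are the mean over tested members of log2(value + 1) minus the mean of the control libraries.

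The genes named were set by a rule fixed before the data were examined: Ctnnb1; up to 8 genes with the largest positive and 8 with the largest negative log2 difference among genes past the adjusted threshold, with a mean of at least 5 units and groups that do not overlap; the 4 members with the smallest p of the WNT target, stem cell, fetal, regeneration and enterocyte lists; and 2 members of each other list with a member past the threshold over all genes, of which there were 0. The rule gave 21 genes. All other genes named were chosen after their values were seen. Results for some genes are not reported here.

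The gene test was tested on simulated data with the real means and spreads of the 11837 genes, in 20 runs with 200 changed genes each. It called 49.3% of genes changed by a log2 of 1, 93.7% at 2, 98.1% at 3 and 99.3% at 4, and 0.09% of unchanged genes. Simulated genes were drawn independently from normal distributions, with no library apart from the others, so these shares need not hold for the data. There, C3 and Saa3 did not pass at log2 differences of 3.00 and 3.26. Unchanged lists of correlated genes were called by camera with the preset correlation in 0.7% of cases at a correlation of 0, 29.7% at 0.3 and 49.4% at 0.7, and in at most 0.09% with an estimated correlation. Lists with a true change were not simulated, so the share of them that camera or fry would call is unknown.

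Same-numbered libraries did not share a label for animal, litter or day, and the main fit had no block. The alternatives set beforehand were rescaling by median of ratios or upper quartile, no filter or a mean of at least 5 units, pseudocounts of 0.1 and 5, array weights, a replicate block, leaving out each library, stricter thresholds, estimated correlation, fry and lists without shared genes. Sex as a covariate, read from Xist and Y-linked genes, was added after seeing the data. Biotypes and gene names came from the GRCm38 reference, and no coordinates are given because the builds differ. The pseudogene transcripts were compared with the other transcripts of that reference with BLAST+ 2.17.0. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.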

Results

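Messenger RNA was measured in primary crypt epithelium of mice, the cell layer lining the crypts of the intestine, where stem cells and Paneth cells reside. 3 libraries came from β-catenin GOF/+ crypts, in which a single allele of the β-catenin gene had been made mutant 4 days earlier, and 3 from control crypts. The series text names signatures of regeneration and of the fetal gut for this comparison, so lists of such genes, with WNT target and stem cell genes, were examined first. The labels do not say whether libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may in part be technical. The deposited values are a normalized abundance per gene, given below as units, and the absolute read depth is unknown. Steps among the lowest values gave the relative number of reads per unit, which ranged from 0.886 in mutant replicate 3 to 1.42 in control replicate 3. Paneth cell alpha-defensins made up 49.8, 34.5 and 24.7% of all units in the 3 control libraries and 16.9, 37.3 and 11.1% in the 3 mutant libraries. Levels of Xist and of Y-linked genes marked 2 control libraries and 1 mutant library as male and the other 3 as female, so each group holds libraries from at least 2 animals.

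The first comparison asked which genes differed between mutant and control crypts. Ctnnb1, which encodes β-catenin, stood at 256 ± 15.1 units in control and 261 ± 24.4 units in mutant libraries (mean ± SD, n = 3 each), a difference below the spread between replicates. The value covers the whole gene and does not measure the mutant allele. Transcripts of 2 pseudogenes fell in mutant crypts. Gm8580 went from 44.9 ± 22.0 to 1.05 ± 0.152 units, a log2 difference of -4.38 ± 0.32 (SE) with an adjusted p of 0.0374 in limma. Gpx2-ps1 went from 44.5 ± 28.7 to 0.670 ± 0.144 units, a log2 difference of -4.60 ± 0.39 with an adjusted p of 0.0445. Both are near copies of other genes, so their values are uncertain. Gm8580 matched the ribosomal protein gene Rpl29 at 96.9% of 449 aligned bases, and Gpx2-ps1 matched the glutathione peroxidase gene Gpx2 at 98.1% of 572 aligned bases. The parent genes did not pass the test: Rpl29 had 650 ± 118 and 718 ± 217 units in control and mutant libraries, and Gpx2 had 748 ± 151 and 1305 ± 660 units (adjusted p of 0.884 and 0.590 in limma).

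No other gene passed. Of 11837 genes tested with limma, 0 rose and 2 fell at an adjusted p under 0.05, while 559 were higher and 425 lower at an unadjusted p under 0.05. The 3 mutant values lay above all 3 control values for 987 genes and below them for 991, together 16.7% of the genes, where chance gives 10%. The 3 genes next in order of p, chosen after their values were seen, were higher in all 3 mutant libraries. Complement C3 had 1.05 ± 0.694 units in control and 14.7 ± 1.86 units in mutant libraries (adjusted p of 0.0596 in limma), the skeletal muscle actin gene Acta1 had 1.50 ± 0.481 and 14.6 ± 5.08 units (0.0624), and the acute-phase gene Saa3 had 0.231 ± 0.0496 and 11.8 ± 5.79 units (0.0935). The adjusted p of the 2 pseudogenes, more than the size of the difference, depended on the libraries kept. When each library was left out in turn, the log2 difference stayed between -4.12 and -4.85 for Gpx2-ps1 and between -4.02 and -4.69 for Gm8580. Neither passed without control replicate 2, where 1 gene rose and 3 others fell, nor without mutant replicate 1, 2 or 3, and Gpx2-ps1 did not pass without control replicate 3 (adjusted p of 0.0823, 0.187, 0.107, 0.0777 and 0.0937 for Gpx2-ps1 in limma, in that order; 0.0823, 0.187, 0.0681 and 0.0751 for Gm8580 in the 4 fits it failed). With array weights, which count libraries far from the others less, 20 genes rose and 7 fell in limma. Those that rose include C3 and Acta1 (adjusted p of 0.00549 each in limma), Saa3, Mgp, Col1a2, Col3a1, Dcn and Sparc. C3 also passed with a pseudocount of 5 (adjusted p of 0.0352 in limma) and without control replicate 2 (0.0372), and Saa3 with a pseudocount of 0.1 (0.0347) and without mutant replicate 1 (0.0281). With sex as a covariate 0 rose and 0 fell.

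**Figure D1:**
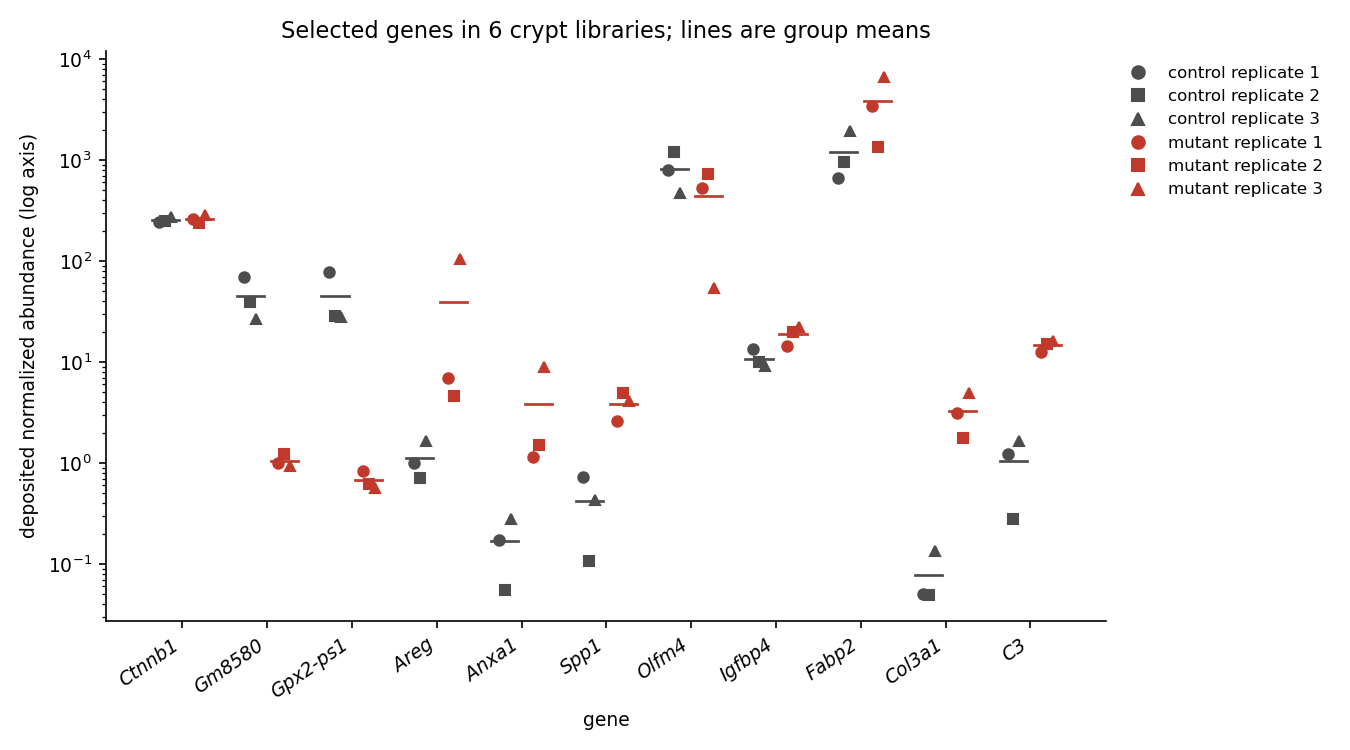
Deposited normalized abundance (log axis) of 11 genes in the 3 control (grey) and 3 mutant (red) libraries; points are libraries and short lines are group means. Ctnnb1 was level at 256 and 261 units, Gm8580 and Gpx2-ps1 were near 1 unit in every mutant library, and Areg and Olfm4 were far from the other libraries in mutant replicate 3.

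Gene lists fixed before the data were examined were then compared as sets with camera. The test called 13 of 23 lists at its preset correlation of 0.01, 11 higher and 2 lower in mutant crypts, and no list held a gene past the adjusted threshold over all genes. With a correlation estimated from the data camera called 0 of them, and fry also called 0. In simulated unchanged lists with a correlation of 0.3 between genes, the preset test called 29.7%, and the median of the estimated correlations here was 0.579. A call with the preset correlation is therefore reported below beside the value with an estimated one, for the fit with all libraries. Fits that left out a library or changed the filter, scaling or covariates used the preset correlation alone. No changed lists were simulated, so whether the estimated correlation or fry could call a true change here is unknown.

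WNT target genes were not called as a set between mutant and control crypts. Axin2, a feedback inhibitor and common readout of WNT signalling, had 28.9 ± 6.85 units in control and 33.5 ± 1.64 units in mutant libraries (n = 3 each). The transcription factor genes Tcf7 and Sp5 had 4.08 ± 0.633 and 1.43 ± 0.151 units in control and 5.65 ± 0.904 and 2.34 ± 0.745 units in mutant libraries, and the adhesion receptor gene Cd44 had 10.7 ± 3.22 and 19.8 ± 10.7 units. Prox1 was the member with the next smallest p, at 1.33 ± 0.320 and 0.877 ± 0.138 units. Of 17 members tested, 10 were higher and 7 lower, 0 passed over all genes and 0 when adjusted over the list alone, and the median log2 difference was 0.06 (camera adjusted p = 0.604; adjusted p = 0.805 with an estimated correlation). The median was -0.27 between male libraries and 0.34 between female libraries. The list was called higher without control replicate 1 (camera adjusted p = 0.0412), and its direction turned without control replicate 3 (0.237) and without mutant replicate 2 (0.901).

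Stem cell genes were mostly lower in mutant crypts without passing the test. Olfm4, a marker of crypt base columnar stem cells, had 822 ± 362 units in control and 439 ± 348 units in mutant libraries, with 54.6 units in mutant replicate 3. Smoc2 had 49.7 ± 4.75 and 29.2 ± 16.8 units, the ion cotransporter gene Slc12a2 had 97.5 ± 32.4 and 65.4 ± 22.6 units, and the stem cell receptor gene Lgr5 had 5.94 ± 1.03 and 4.19 ± 2.48 units. Igfbp4, an insulin-like growth factor binding protein gene, stood the other way at 10.8 ± 2.26 and 18.7 ± 3.94 units. Of 17 members, 13 were lower and 4 higher, 0 passed over all genes or when adjusted over the list alone, and the median log2 difference was -0.26 (camera adjusted p = 0.175; adjusted p = 0.805 with an estimated correlation). Between male libraries the median was -0.41, and between female libraries -0.02. The list was called lower without control replicate 3 (camera adjusted p = 0.00373) and without mutant replicate 2 (0.0134). Without mutant replicate 3 the median was -0.105 (camera adjusted p = 0.759) and the log2 difference of Olfm4 went from -1.46 to -0.298.

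Fetal intestinal genes were called higher as a set in mutant crypts, and mutant replicate 3 scored far above the other libraries. Osteopontin, encoded by Spp1, had 0.420 ± 0.307 units in control and 3.87 ± 1.19 units in mutant libraries, and it was the 1 member that passed when adjusted over the list alone (adjusted p = 0.00267 in limma; 0.249 over all genes). The annexin genes Anxa1 and Anxa3 had 0.169 ± 0.112 and 1.85 ± 1.05 units in control and 3.86 ± 4.39 and 9.32 ± 9.75 units in mutant libraries, and the growth factor gene Igf2 had 0.419 ± 0.119 and 3.06 ± 2.70 units. All 9 members with a mean of at least 1 unit were higher, by a median log2 of 1.29 (camera adjusted p = 0.000124; adjusted p = 0.643 with an estimated correlation), and 0 passed over all genes. Mean scores of the list were 0.31, 0.51 and 2.69 in the 3 mutant libraries and 0.31, -0.29 and -0.02 in the 3 control libraries. Scores of stromal genes were 1.26, 0.93 and 1.91 in the same 3 mutant libraries, and mutant replicate 3 also had the highest scores for immune (1.22), interferon (1.95) and inflammation (2.39) genes. The median of the fetal list was 0.50 between male and 1.53 between female libraries. Without mutant replicate 3 the median was 0.404 and the list was not called (camera adjusted p = 0.243), nor was it with genes of a mean of at least 5 alone (0.287).

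Regeneration genes, which overlap the fetal list and mark epithelium after injury, were likewise called higher as a set. Amphiregulin, an EGF receptor ligand encoded by Areg, had 1.12 ± 0.476 units in control libraries and 6.86, 4.60 and 106 units in mutant replicates 1, 2 and 3. Anxa2 had 382 ± 66.7 units in control and 756 ± 384 units in mutant libraries. The surface marker gene Ly6a had 2.62, 5.15 and 365 units in the 3 mutant libraries against 18.2, 3.48 and 5.54 units in control libraries, and Clu, a marker of revival stem cells, had 2.51, 2.99 and 15.9 against 3.88, 1.70 and 2.49 units. Of 18 members, 17 were higher, 7 of them with all 3 mutant values above all 3 control values, by a median log2 of 0.98 (camera adjusted p = 8.02e-05; adjusted p = 0.643 with an estimated correlation). 0 members passed over all genes and 0 when adjusted over the list alone. The median was 0.31 between male libraries, 1.08 between female libraries and 0.32 without mutant replicate 3, where the call was lost (camera adjusted p = 0.0613). Targets of the regulator YAP were called higher (median log2 of 0.28 over 13 members, camera adjusted p = 0.0328; adjusted p = 0.759 with an estimated correlation) and were not called without mutant replicate 3 (0.810, with a median log2 of 0.0164) or control replicate 2 (0.0713), with a mean of at least 5 units (0.225) or with the sex covariate (0.0934).

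The mean scores of 4 lists of stress and signalling genes lay above those of all control libraries in all 3 mutant libraries. Of 12 target genes of the tumour suppressor p53, 10 had every mutant value above every control value, and the list was called higher by a median log2 of 0.98 (camera adjusted p = 3.98e-07; adjusted p = 0.643 with an estimated correlation). The stress response gene Sesn2 had 2.70 ± 0.364 units in control and 7.15 ± 2.55 units in mutant libraries, Phlda3 had 0.271 ± 0.154 and 11.3 ± 13.2 units, and the cell cycle inhibitor gene Cdkn1a had 49.2 ± 6.97 and 159 ± 129 units; Sesn2 and Phlda3 were the 2 that passed when adjusted over the list alone. Immediate early genes, which respond within minutes to growth factors, stress and tissue handling, were called higher by a median log2 of 0.86 over 13 members (camera adjusted p = 6.53e-06; adjusted p = 0.643 with an estimated correlation). Egr1 had 2.36 ± 0.974 and 9.41 ± 3.02 units and was the 1 that passed over the list alone, and Fos had 14.0 ± 5.97 and 57.2 ± 39.4 units. Inflammation genes were called higher by a median log2 of 0.91 over 13 members (camera adjusted p = 8.02e-05; adjusted p = 0.643 with an estimated correlation), with Saa3 alone past the threshold over the list alone; the antimicrobial lectin gene Reg3g had 1820 ± 1562 and 6098 ± 3981 units. Ligands secreted by epithelium were called higher by a median log2 of 0.47 over 14 of 30 members (camera adjusted p = 0.000742; adjusted p = 0.643 with an estimated correlation), with Spp1 alone past it. Of the untested ligands, Shh (means of 0.178 and 0.0313 units) and Fgf9 (1.03 and 0.672 units) were below every control value in every mutant library. Wnt10a (0 and 0.0799 units) was above. This list lost its call without genes shared with other lists (camera adjusted p = 0.0676) and with a mean of at least 5 units (0.0574). With the preset correlation the 4 lists kept their calls without mutant replicate 3, at adjusted p of 1.29e-08, 3.17e-06, 0.0170 and 0.00500 in camera. The median log2 differences were then 0.55, 0.42, 0.28 and 0.07. This fit was not run with an estimated correlation, which with all libraries was 0.87, 0.37, 0.58 and 0.40 for these lists. Over all genes, 0 members of these lists passed. Stromal genes, which mark another cell type, were higher in the same 3 mutant libraries, with scores of 1.26, 0.93 and 1.91 against -0.19 to 0.16 in control libraries.

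**Figure D2:**
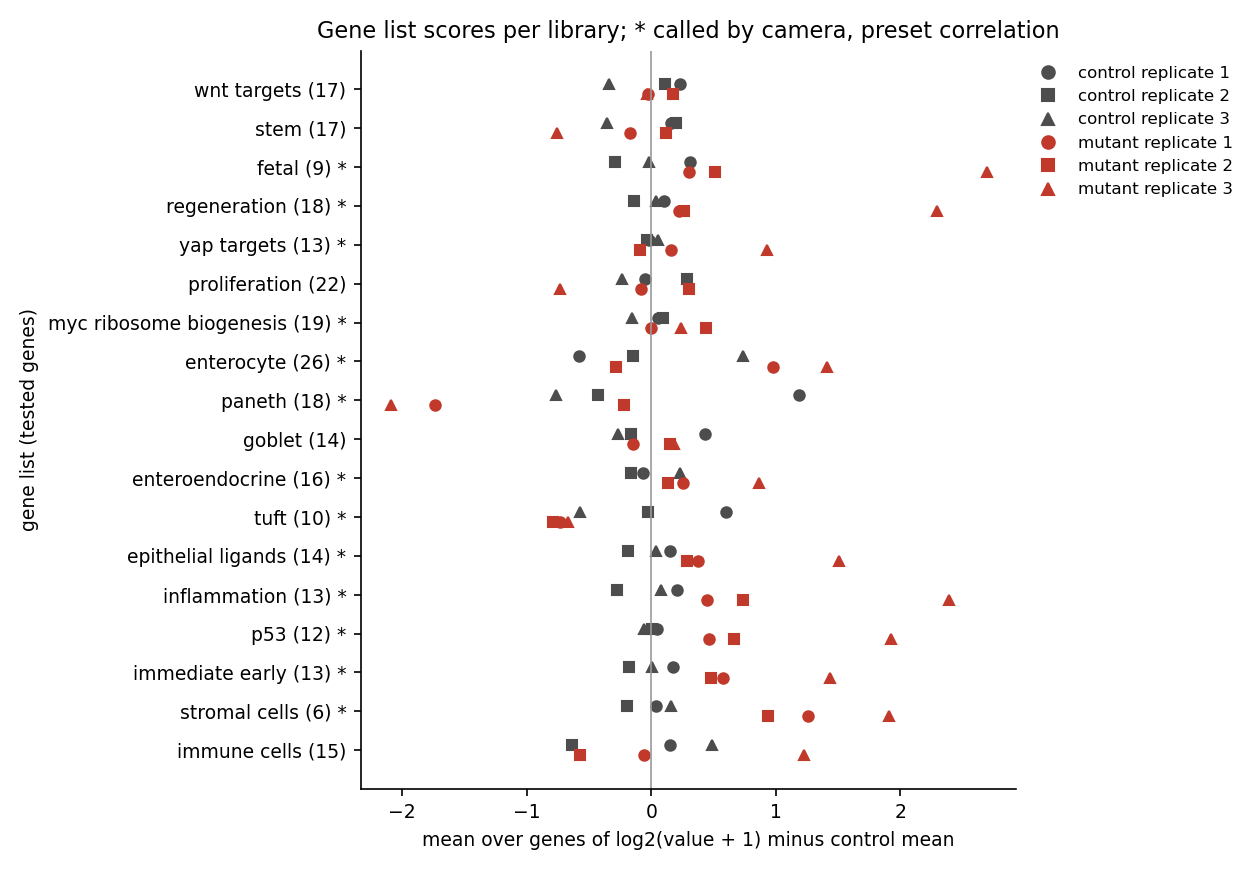
Scores of 18 gene lists in each library, as the mean over tested genes of log2(value + 1) minus the mean of the 3 control libraries; grey points are control and red points are mutant libraries, and an asterisk marks a list called by camera with its preset correlation. Mutant replicate 3 had the highest score for fetal (2.69) and regeneration (2.29) genes, while stromal genes scored 1.26, 0.93 and 1.91 in the 3 mutant libraries.

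Among the mature cell types, enterocyte genes were called higher and Paneth and tuft cell genes lower. Fabp2, a fatty acid binding protein gene of absorptive cells, had 1188 ± 672 units in control and 3817 ± 2685 units in mutant libraries, Krt20 had 340 ± 171 and 851 ± 547 units, Apoa1 had 1290 ± 815 and 3779 ± 3051 units, and the disaccharidase gene Treh had 36.2 ± 25.4 and 84.6 ± 53.7 units. Of 26 enterocyte genes, 24 were higher by a median log2 of 0.62 (camera adjusted p = 0.000124; adjusted p = 0.728 with an estimated correlation), and the median was 1.41 between male and -0.10 between female libraries. The enterocyte scores overlapped between the groups, at -0.58, -0.15 and 0.73 in the 3 control and 0.98, -0.28 and 1.41 in the 3 mutant libraries. Of these genes, 0 had every mutant value above every control value. Without mutant replicate 3 the median was 0.326 (camera adjusted p = 0.0360). The log2 difference then went from 1.55 to 1.00 for Fabp2 and from 1.22 to 0.729 for Krt20. All 18 Paneth cell genes were lower by a median log2 of -1.18 (camera adjusted p = 1.07e-05; adjusted p = 0.643 with an estimated correlation), with 0 of them below every control value in every mutant library. Many are alpha-defensin genes of a single family, and the estimated correlation was 0.858, so the members are not separate observations. The list also holds Pla2g2a (log2 difference of -3.57), which was high in control replicates 1 and 3 alone and counts toward the mean difference below. The ribonuclease gene Ang4 had 9878 ± 9029 and 1714 ± 1570 units. The Paneth median was -2.21 between male and -0.23 between female libraries. Scores were 1.19, -0.43 and -0.76 in the 3 control and -1.74, -0.22 and -2.09 in the 3 mutant libraries, and the mean log2 difference went from -1.35 to -0.76 without control replicate 1 (camera adjusted p = 0.00490). All 10 tuft cell genes were lower by a median log2 of -0.72 (camera adjusted p = 1.07e-05; adjusted p = 0.643 with an estimated correlation), -0.92 between male and -0.12 between female libraries. Their scores were 0.60, -0.03 and -0.57 in control and -0.74, -0.79 and -0.67 in mutant libraries, and the mean log2 difference went from -0.73 to -0.43 without control replicate 1 (camera adjusted p = 0.000267). The lipoxygenase gene Alox5 had 5.60 ± 2.75 and 2.03 ± 0.191 units, and the kinase gene Dclk1 had 8.07 ± 4.01 and 3.85 ± 0.793 units. No enterocyte, Paneth or tuft cell gene passed over all genes or when adjusted over the list alone.

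Enteroendocrine genes moved both ways, and goblet cell genes were not called. Of 16 enteroendocrine genes, 12 were higher and 4 lower, by a median log2 of 0.46 (camera adjusted p = 0.000907; adjusted p = 0.643 with an estimated correlation). When adjusted over the list alone, 2 were higher and 1 lower at an adjusted p of 0.0248 in limma each, and 0 passed over all genes. The secretin gene Sct had 18.7 ± 4.02 units in control and 59.5 ± 33.4 units in mutant libraries, the granin gene Chgb had 91.7 ± 8.07 and 144 ± 14.6 units, and the ghrelin gene Ghrl had 34.0 ± 8.48 and 16.3 ± 3.35 units. Of 14 goblet cell genes, 8 were higher and 6 lower (median log2 of 0.07, camera adjusted p = 0.604), and the mucin gene Muc2 had 293 ± 117 and 394 ± 80.1 units. The goblet list was called higher without control replicate 1 (camera adjusted p = 0.0298). Proliferation genes were not called (18 of 22 lower, median log2 of -0.19, camera adjusted p = 0.180), with Mki67 at 58.5 ± 17.4 and 41.4 ± 18.0 units. They were called lower without control replicate 3 (camera adjusted p = 0.0193) or mutant replicate 2 (0.000524). Ribosome biogenesis genes regulated by MYC were called higher by a median log2 of 0.27, with 18 of 19 members up (camera adjusted p = 0.00100; adjusted p = 0.670 with an estimated correlation). Their median was -0.09 between male and 0.51 between female libraries, and the call was lost without control replicate 3 (camera adjusted p = 0.0699) or mutant replicate 2 (0.222).

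Genes of other cell types also differed between the libraries. Several stromal genes had less than 1 unit in control libraries and more in every mutant library. The collagen genes Col1a2 and Col3a1 had 0.0299 ± 0.0406 and 0.0779 ± 0.0482 units in control and 2.18 ± 0.799 and 3.27 ± 1.60 units in mutant libraries, and the matrix protein genes Dcn and Sparc had 0.612 ± 0.355 and 0.175 ± 0.137 units in control and 5.06 ± 1.89 and 2.70 ± 1.26 units in mutant libraries. These 4 passed when adjusted over the list alone, and 0 passed over all genes. Vim and Tagln were well above 0 in control libraries as well, at 5.73 ± 1.05 and 2.48 ± 0.630 units, with 9.84 ± 4.31 and 4.41 ± 2.56 units in mutant libraries. All 6 stromal genes with a mean of at least 1 unit were higher by a median log2 of 1.61 (camera adjusted p = 7.76e-08; adjusted p = 0.643 with an estimated correlation), with 1.49 between male and 1.57 between female libraries. The list kept its call without mutant replicate 3 (camera adjusted p = 6.29e-05). Immune genes had a median log2 of 0.18 over 15 members and were not called (camera adjusted p = 0.392), with scores of -0.06, -0.58 and 1.22 in the 3 mutant libraries; without mutant replicate 2 they were called higher (0.0155). Genes of the interferon response and of antigen presentation by MHC class II were not called (camera adjusted p = 0.392), were called higher without mutant replicate 2 (0.00797) and were called lower without mutant replicate 3 (0.00163).

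The remaining lists gave no call. Markers of the distal intestine (6 tested, median log2 of 0.11, camera adjusted p = 0.604) held members that stood in opposite directions. The ileal bile acid binding protein gene Fabp6 had 156, 5.74 and 74.2 units in the control and 174, 388 and 1101 units in the mutant libraries. Slc10a2 had 3.53 ± 1.39 and 13.9 ± 12.7 units, and the carbonic anhydrase gene Car4 had 297 ± 89.2 and 177 ± 31.5 units. Distal scores were 0.33, -0.65 and 0.32 in the 3 control and 0.54, 0.43 and 1.00 in the 3 mutant libraries, with 3 members higher and 3 lower. Whether the groups differ in intestinal region was not tested. Markers of the proximal intestine (7 tested, median log2 of -0.15, camera adjusted p = 0.755), erythroid genes (5 tested, median log2 of 0.52, camera adjusted p = 0.755) and the genes used to read sex (5 tested, median log2 of -1.05, camera adjusted p = 0.448) were not called. Of the proximal markers 3 were higher and 4 lower, and Onecut2 (4.78 ± 1.38 and 2.39 ± 0.757 units) was below every control value in every mutant library. Of the secreted WNT antagonists 1 had a mean of at least 1 unit (Sfrp5, 1.08 ± 0.171 and 1.22 ± 0.917 units), and of the endothelial genes 2 did. Neural and glial genes had 0 tested members, and the mitochondrial genes were not found under their names, so these 4 lists have no test.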

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

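Sex was read from the data after they were seen, and the difference between the sexes was not tested. For 3 of 22 lists and 0 of 21 named genes, every mutant library lay on opposite sides of every control library in the 2 sexes, where chance with so few libraries gives 22.2% of items. WNT target genes had a mean log2 difference of -0.20 between male and 0.41 between female libraries (male minus female -0.61). For ribosome biogenesis genes regulated by MYC these were -0.08 and 0.50 (male minus female -0.58), and for proximal intestine genes 0.26 and -0.36 (male minus female 0.62). The male comparison rests on 1 mutant and 2 control libraries and the female one on 2 mutant and 1 control library.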

How the results depend on the processing

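Sex as a covariate was added after seeing the data; the other alternatives were planned. Under 15 other fits the 2 pseudogene calls both stayed in 6 and were both lost in 8, always with lower values in mutant libraries. Genes that rose and fell numbered 20 and 7 with array weights, 1 and 2 with a pseudocount of 0.1, and 1 and 0 with a pseudocount of 5. There were 0 lower genes without a filter, with the replicate block, with the sex covariate and at an adjusted p under 0.01. Leaving out each library gave 0 to 2 higher and 0 to 3 lower genes. Whether the numbers pair the libraries stays open. Same-numbered libraries correlated at -0.29, 0.33 and 0.32, and pairs with different numbers at -0.49 to 0.21. Of 6 libraries, 4 correlated best with their own number. With the replicate block 15 lists were called, the stem cell (camera adjusted p = 0.0140) and proliferation (0.0193) lists as lower. The fetal list was not called with a mean of at least 5 units (0.287). Fetal and regeneration lists were not called with an estimated correlation (0.643 each) or by fry (0.443 and 0.555), and the number of lists called was 0 under both. Leaving out each library moved the adjusted p from 0.0412 to 0.901 for WNT targets, 0.00373 to 0.759 for stem cell, 4.94e-06 to 0.243 for fetal and 1.44e-06 to 0.0613 for regeneration genes, and the number of lists called from 11 to 16. Lists that turned direction were not called with all libraries. The proximal intestine list turned with a mean of at least 5 units (0.441). When libraries were left out in turn, the adjusted p ranged from 0.314 to 0.895 for this list (turned without control replicate 3 or mutant replicate 2), 0.0298 to 0.945 for goblet (control replicates 2, 3), 0.00163 to 0.749 for interferon and 0.0155 to 0.745 for immune genes (both control replicate 2, mutant replicate 3), 0.0793 to 0.931 for erythroid (mutant replicate 1) and 0.000524 to 0.895 for proliferation genes (mutant replicate 3). The log2 difference of Ctnnb1 ranged from -0.0356 without mutant replicate 3 to 0.099. The cause was not tested for any of these. DESeq2, edgeR and voom were not run, since the values are not counts. Unknown depth limits what can be said of genes under 1 unit.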

Other observations

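The fibroblast genes' comparison with markers of other cell types and with depth, the tests of the pseudogenes, of mutant replicate 3 and of the split for called genes were chosen after the results were seen; the held-out fibroblast test and the split for lists were written before.

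Several fibroblast transcripts were higher in all 3 mutant libraries. Of 25 further fibroblast genes whose values had not been looked at, 10 had every mutant value above every control value, 0 had every value below and 15 did not separate the groups, where chance gives 5% (one-sided exact binomial p = 1.59e-07, which treats genes as independent). Carry-over of stromal cells or their RNA may therefore account for the pattern, although the levels were low. Dcn had 5.06, Col3a1 3.27 and Col1a2 2.18 units in mutant libraries. The 10 further genes that separated the groups had mutant means from 0.0224 (Col12a1) to 0.797 units (Fbln2). Fbln1, Thy1 and Pcolce, with control means above 1 unit, did not separate them. Whether a lower purity raised every other cell type alike could not be decided. The stromal markers had been singled out by their rise, the other markers had not, and all compared markers were near the floor in control libraries. At a control mean under 1 unit, 11 of 14 stromal markers had every mutant value above every control value, against 4 of 17 immune, endothelial and neural markers (Fisher's exact p = 0.00385, two-sided). The 4 markers (Adgre1, Plvap, Tubb3 and Uchl1) were more than the 5% of chance (one-sided exact binomial p = 0.00880, which treats genes as independent). That share is a low bar here, as it is for the 25 further genes. Of 11837 tested genes, 987 had every mutant value above every control value, where 5% would be 592. A rise of other cell types stays open. Deeper mutant libraries are argued against, since the mutant library had fewer reads per unit in 7 of 9 pairs of a mutant and a control library. Expression of these genes by mutant epithelial cells and a change in the stroma next to mutant crypts stay open.

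Mutant replicate 3 stood apart. 91 genes were at least 4-fold above the other 5 libraries in it, against at most 2 in any other library. Added cells cannot raise a gene by a larger fold than the genes they express most purely. Neither marker list below was shown to hold such genes. Over the highest of the other libraries, the median log2 gain was 1.84 for 18 regeneration genes and 0.377 for 26 enterocyte genes (one-sided permutation p = 1e-05 over genes). The comparison was chosen because regeneration genes were high in this library. Enterocyte genes were already abundant in control libraries, with means from 24.8 (Cyp3a11) to 1290 units (Apoa1), which limits their gain. The comparison therefore cannot decide whether more villus tissue was the cause. Immune genes were also high in it (14 of 15 were highest there), but their median log2 gain of 0.556 was below that of regeneration genes as well (one-sided permutation p = 0.00075 over genes). Immune genes had control means from 0.699 (Ms4a1) to 61.7 units (Gzma), which limits the gain of those already high. The comparison therefore cannot decide about lymphoid cells either. Both p-values treat genes as independent. A more distal piece of intestine (Fabp6 was highest there, at 1101 units), a stronger response to the mutant allele in that library, injury and a mislabelled sample stay open, untested.

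Gpx2-ps1 and Gm8580 were nearly absent from mutant libraries. Reads shared with the parent gene at a fixed share would keep the ratio to the parent level, but it was lower in every mutant library for both. This followed from the fall of the pseudogenes beside parents whose means did not fall, so it is no separate support. A share that varies between libraries was not tested. The mutant minus control difference of the log2 ratio was -7.9 pooled SDs for Gpx2-ps1 and -8.61 for Gm8580, which went from 5.65 to 0.0649% of Gpx2 and from 7.32 to 0.151% of Rpl29. A genetic background that differs between the mice is a candidate explanation. Of 16 genes that step at least 4-fold between other groupings of the libraries, 13 have an annotated biotype and 5 of these are pseudogenes, against 102 of 11684 tested genes (Fisher's exact p = 5.59e-08, two-sided). The 16 step genes include the MHC gene H2-L, at 96.7 and 97.9 units in control replicates 1 and 3 and at most 0.875 in the other libraries. The phospholipase gene Pla2g2a, annotated as a pseudogene and counted among the 5, had 17760 and 3725 units in the same libraries and at most 234 in the rest. These groupings leave out genotype, so they do not show a background that differs along it. A division of reads between near copies that varies between libraries could also favour pseudogenes and was not tested. An effect of the mutant allele on the 2 pseudogenes stays open, untested.

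With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 2 genes and the highest other 5, which was the split by sex and called Xist and 4 Y-linked genes. With the real one counted, 2 of the 10 splits called at least as many genes as the real one. At an unadjusted p under 0.05 the real split had 984 genes and the highest other 1758, with control replicates 1 and 2 and mutant replicate 2 against the rest, so the libraries also differ along lines other than genotype. For lists the real split called 13 and the highest other 19, again the split by sex, and 7 of the 10, the real one included, called at least as many.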
